A study of Mus musculus with 4 samples.

How the data were processed

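Expression was measured in 4 samples of BAX/BAK-deficient, SV40-transformed mouse embryonic fibroblasts: cells with a GFP or a p63 retrovirus, each mock-treated or treated with etoposide for 6 h. Per the labels' protocols, total RNA was extracted with Trizol, amplified and biotin-labelled with a NuGEN whole-transcriptome kit for picogram amounts of RNA, and hybridised to Affymetrix Mouse Gene ST arrays. Samples were grouped by the virus and treatment in their labels, which give 1 array per group. The labels disagree on the dose of etoposide: the treatment protocol gives 10 µg/mL, and the sample characteristics and design text give the same number per microlitre. The design text lists the etoposide-treated GFP cells again where the last sample stands, and that sample's own labels name p63 and etoposide, which were used. The species and isoform of the p63 construct are not given in the sources used here.

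The deposited values are on a log2 scale and were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, and the version is not given in the sources used here. RMA subtracts a modelled background, makes the probe intensity distributions of all arrays equal and summarises probes per probe set, so a shift shared by most genes of an array is largely removed before deposit. The log base was inferred from the range of the values, 1.27 to 14.4 over all arrays. The SD over all probe sets was 2.39, 2.37, 2.28 and 2.38 on the arrays of mock-treated GFP, etoposide-treated GFP, mock-treated p63 and etoposide-treated p63 cells. Arrays give no counts, and their number limits the precision.

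The table held 35512 probe sets. A platform annotation of 2016 gave exactly 1 gene symbol for 21789, several for 1621, and did not list 12102, which are unnamed here. Symbols were checked through their Entrez identifiers against a RefSeq gene table (GRCm38.p6), in which 21698 of the 21789 matched. The genome build of the array annotation is not given in the sources used here, so no coordinates are given, and the RefSeq table served for names, gene types and gene lengths only. Of several probe sets of a gene, the one with the highest mean over the 4 arrays was used, which left 19938 genes. A gene was kept where its highest value reached the 50th percentile of all values of these probe sets, 5.87, which left 10698 genes.

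With 1 array per group there is no spread between replicates, so no test was made and no p-value is given. An additive model of treatment and virus would leave 1 residual degree of freedom and take any true interaction for noise, and was not used. The comparisons were etoposide minus mock in each line, p63 minus GFP under each treatment, and the difference of the etoposide differences. A gene was called higher or lower at a difference of at least 1. For each effect the genes called in both of its pairs were counted beside the number that independent lists of the same sizes would share, and Pearson and Spearman correlations of the differences were taken across genes. For each of 25 gene lists, the median difference over the members kept was placed among the medians of 10000 random lists of the same size, drawn to match its members' mean expression in 10 bins. This percentile describes these arrays and is no test of the conditions. The same 25 lists were examined for 2 pair means, and 23 of the 50 percentiles lay outside the middle 95%. An array was said to stand apart for a gene where it lay at least 1 from each of the other arrays and those lay within 0.5 of one another.

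The lists covered p53 targets, epithelial genes bound or regulated by p63, the BCL-2 family, death receptors with caspases and necroptosis, cathepsins and lysosome, redox, DNA repair, G2/M, S phase, immediate early genes, NF-kB and inflammation, interferon-stimulated genes, the unfolded protein and ATF4 response, autophagy, replication-dependent histones, heat shock, cholesterol synthesis, fibroblast matrix and the Notch pathway. Markers of simple epithelium, haematopoietic cells, endothelium, skeletal muscle, adipocytes and neural cells completed them. Genes were named by a rule. It took Trp63, Trp73, Bak1, Bax and Trp53, then the 12 most raised and the 12 most lowered genes by mean difference among those called in both pairs, and the 8 highest and 8 lowest values of the difference of differences. It also took the 5 highest and 5 lowest genes of each single comparison and, from each list, the members called in both pairs or, where there were none, the up to 4 with the largest mean difference. Clone and predicted names, olfactory and vomeronasal receptors and small RNAs named by number were counted but not named under the ranking parts. The rule named 203 genes. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

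The alternatives were no filter, a filter at the 75th percentile (7.82), a 1.5-fold threshold, the median of a gene's probe sets, arrays centred on the median of the genes kept, cyclic loess between the arrays, and values under the filter raised to it. Results without the array of mock-treated p63 cells were added after that array was seen to stand apart. Also added after the data were seen were list medians and the overlap of the effects with values raised to the filter and, for the number of genes by which an array stood apart, arrays centred and cyclic loess with each array's median put back as deposited. The procedure was tested on simulated data for 10552 genes with noise of SD 0.227 per array, which is the SD of the difference of differences divided by the square root of the number of arrays and includes any true interaction. Etoposide changes of 1, 1.5, 2 and 3 (log2) in both pairs were called for 18%, 88%, 90% and 92% of 50 genes each, and p63 changes for 22%, 86%, 90% and 98%. Of 10152 unchanged genes, 0 were called in both pairs of either effect, and 14 (0.14%) for etoposide and 13 (0.13%) for p63 in 1 pair only. The simulation gave bright and dim genes and all arrays the same noise, without a shift in an array's level. These rates therefore need not hold for the measured arrays, of which 1 stood apart. For the overlap of the etoposide and p63 calls, unchanged groups with the same noise were simulated 100 times. A fold against a reading below the filter was computed with that reading raised to the filter, as a lower bound, since the filter stands in for a detection limit. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3 with limma 3.58.1 for cyclic loess, and matplotlib 3.10.9 for figures.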

Results

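The series measured gene expression in mouse embryonic fibroblasts (MEFs) that lack BAX and BAK, the effector proteins that permeabilise the outer mitochondrial membrane during apoptosis. The cells were of C57BL/6 background and had been transformed with SV40, a virus whose large T antigen binds p53 and the retinoblastoma protein. They carried a retrovirus for GFP, the control, or for p63, a transcription factor of the p53 family that is required for the formation of stratified epithelia. Each line was mock-treated or exposed for 6 h to etoposide, a drug that traps topoisomerase II on cleaved DNA. Total RNA from the 4 conditions was hybridised to Affymetrix Mouse Gene ST arrays, with 1 array per condition. Values are the deposited RMA signals on the log2 scale, so a difference of 1 is a 2-fold change. Of 19938 named genes, 10698 reached the brightness filter on at least 1 array, and the median of these was 7.69 in mock-treated GFP cells, 7.60 in etoposide-treated GFP cells, 7.48 in mock-treated p63 cells and 7.68 in etoposide-treated p63 cells.

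No condition was replicated, so differences are given by their size, without a test or an error. A gene is called higher or lower where the difference reached 1 (log2). Each treatment was compared in a pair of cell lines and each virus under a pair of treatments, and the comparisons within such a pair share no array. Agreement between them is the check on size that the design offers. Both p63 comparisons use the same GFP and p63 lines, so their agreement does not separate p63 from another difference between those lines. Across the genes kept, the etoposide difference in p63 cells minus that in GFP cells had an SD of 0.45, and its size was under 0.94 for 95% of genes. The number of arrays limits the precision of every value. Of 200 named genes kept, 65 read below the filter of 5.87 on at least 1 array. Their log2 differences rest on signal near background, and a fold against such a reading is given as a lower bound, with that reading raised to the filter. With these readings raised, 69 of 80 named genes called in both lines after etoposide were still called, and 30 of 46 with p63 under both treatments.

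The targeted genes were examined on every array. The Trp63 signal was 4.87 and 5.59 in GFP cells and 8.75 and 9.29 in p63 cells, in the order mock and etoposide, a difference of 3.88 in mock-treated and 3.70 in etoposide-treated cells. The GFP readings were below the filter, so the arrays labelled p63 carried at least a 7.36-fold and a 10.7-fold higher Trp63 signal. Trp73, the related family member, read 5.24, 5.59, 6.16 and 6.24 on the 4 arrays in the same order. Bak1, disrupted in these cells, stayed below the filter of 5.87 on all arrays, at 5.43, 5.41, 5.71 and 5.45. Where its probes lie relative to the disrupted part is not given in the sources used here, so this reading does not check the genotype. Bax and Trp53 were not analysed here.

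The comparison of etoposide with mock treatment asks how cells that lack BAX and BAK respond to DNA damage. After 6 h of etoposide, 22 of 37 genes that p53 activates were higher in both lines, and 10 of 37 genes of the G2/M phases were lower in both. Mdm2, the ubiquitin ligase that restrains p53, was higher by 2.40 in GFP cells and 2.59 in p63 cells, or 5.28-fold and 6.01-fold. Fas, a death receptor, was higher by 2.59 and 2.39, and Btg2, an antiproliferative gene, by 2.75 and 2.41. Plk1, a kinase required for mitosis, was lower by 5.23-fold in GFP cells and 5.19-fold in p63 cells, with log2 differences of -2.39 and -2.38. Adamts5, a protease that cleaves aggrecan, had the lowest difference of the genes kept in GFP cells, at -3.02, and stood at -2.31 in p63 cells.

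In GFP cells 604 genes differed by at least 1 after etoposide, 377 of them higher and 227 lower. In p63 cells 814 genes did so, 672 higher and 142 lower. The lists shared 275 higher and 65 lower genes, where independent lists of these sizes would share 23.7 and 3.01, and 1 gene was called in opposite directions. With readings below the filter raised to it, 274 genes were shared, 221 higher and 53 lower. Across genes the etoposide differences in the lines had a Pearson correlation of 0.629 and a Spearman correlation of 0.520, where genes are not independent replicates. Besides Mdm2, Fas and Btg2, the shared genes with the highest mean difference included Tuba8, an alpha-tubulin, at 2.96 and 2.81, and Ces2g, a carboxylesterase, at 2.68 and 2.65 in GFP and p63 cells. Ddit4l, a relative of the mTORC1 inhibitor Ddit4, was higher by 2.46 and 2.74, and Apobec1, the cytidine deaminase that edits apolipoprotein B mRNA, by 2.36 and 2.81. Tex15 (2.48 and 2.71), Mab21l3 (2.86 and 2.25), Depdc7 (2.97 and 2.10), Nipal4 (2.82 and 2.23) and Slc19a2 (2.08 and 2.85), the last a thiamine transporter, completed the 12. Of these, 5 read below the filter on at least 1 array, and with such readings raised to it Tex15 stood at 1.33 and 1.51, Ces2g at 1.53 and 2.65, Mab21l3 at 2.04 and 2.25, Tuba8 at 2.45 and 2.16, and Nipal4 at 2.52 and 2.23. Rgcc and Glyat were among the 5 highest in GFP cells, with 2.87 and 2.84, and also stood higher in p63 cells, by 1.72 and 2.01. Glyat read below the filter on 3 arrays, and its differences were 0.20 and 0.00 with these readings raised to it.

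**Figure D1:**
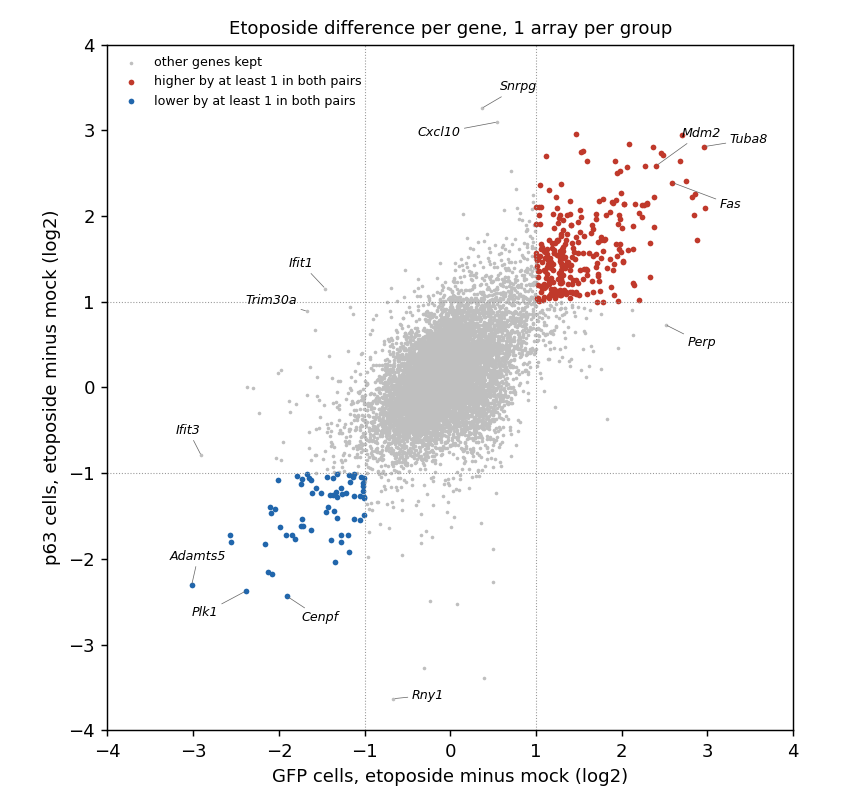
Each point is 1 of the 10698 genes kept, with its etoposide minus mock difference (log2) in GFP cells on the x axis and in p63 cells on the y axis. The 275 genes higher and the 65 genes lower by at least 1 in both lines are coloured, and dotted lines mark differences of -1 and 1.

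Of the 37 p53 target genes kept, 22 were higher in both lines and 0 were lower in either, and the list's median difference was 1.34 in GFP cells and 1.67 in p63 cells. The mean of the pair lay above all of 10000 random lists matched on expression (percentile 100). Members included Pmaip1, which encodes the BH3-only protein NOXA, at 2.15 and 2.14, Eda2r, a receptor of the TNF family, at 2.06 and 2.57, and Trp53inp1 at 2.29 and 2.14. The damage-tolerance polymerase gene Polk was higher by 1.36 and 2.01, Zmat3 by 1.53 and 1.99, and Apaf1, the scaffold of the apoptosome, by 1.71 and 1.00.

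The G2/M list showed the opposite direction, with 10 of 37 members lower in both lines, medians of -0.93 and -0.71, and a pair mean at percentile 0.00. Aurka, a spindle-pole kinase, stood at -1.74 and -1.62, Cenpf, a kinetochore protein gene, at -1.91 and -2.44, and Nusap1 and Prc1, which bind spindle microtubules, at -2.17 and -1.83 and at -1.91 and -1.72. Kif18a, a mitotic kinesin outside the list, was at -1.99 and -1.63. Replication-dependent histone genes had medians of -0.85 and -0.94 (percentile 0.00), though only 2 of 21, H1f2 and H2bc3, were lower by at least 1 in both lines. S phase and replication genes leaned the other way, with medians of 0.16 and 0.43 and a percentile of 100, and 1 of 41, Rrm2, a subunit of ribonucleotide reductase, was higher in both lines (1.19 and 1.63). The remaining lowest shared genes were outside the cell cycle lists. They comprised Pcdh18 (-2.56 and -1.80), Lurap1l (-2.57 and -1.72), Aspn (-2.13 and -2.16), which encodes a small proteoglycan, Trps1 (-2.08 and -2.17), a GATA-type repressor, Sema3a (-1.82 and -1.77), a guidance cue, and Npy1r (-1.85 and -1.72), a neuropeptide Y receptor. Aspn and Npy1r were dim, and with readings below the filter raised to it stood at 0.00 and -0.55 and at -0.55 and -1.59, so neither was called in both lines.

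Immediate early genes had medians of 0.41 in GFP cells and 0.96 in p63 cells (percentile 100), with 7 of 36 higher in both lines and 0 lower in either. Among them were Fos at 1.60 and 2.64, Atf3 at 1.98 and 1.96, and Dusp6, a phosphatase of ERK, at 1.47 and 2.96. NF-kB and inflammatory genes had medians of 0.39 and 0.82 (percentile 100), and 5 of 25 were higher in both lines: Nfkbia, the NF-kB inhibitor, at 1.05 and 2.36, Ccl2 at 1.04 and 2.11, Icam1 at 1.34 and 1.40, Lif at 1.79 and 1.59, and Csf2 at 1.59 and 1.37. The list of death receptors, caspases and necroptosis genes had medians of 0.11 and 0.38 (percentile 99.2), with Fas higher and Casp12 lower (-1.02 and -1.15) in both lines. With readings below the filter raised to it, 5 immediate early and 4 NF-kB genes were higher in both lines, Fos (0.85 and 1.75) was no longer so called, and Csf2 (0.25 and 0.22) and Casp12 (-0.81 and -0.67) did not reach 1. Without a filter the pair median of the NF-kB list was 0.277, against 0.535 with it.

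Interferon-stimulated genes were lower after etoposide in GFP cells, with a median of -0.99 and 18 of 36 members lower by at least 1. With readings below the filter raised to it, the median of these genes in GFP cells was -0.71. In p63 cells their median was 0.04 against 0.10 for all genes kept, and 4 members were higher and 1 was lower by at least 1. That median takes the opposite sign once arrays are centred, since centring moves the etoposide difference of all genes in p63 cells from 0.10 to -0.10. Ifit2 (-1.004 and -1.293) was lower in both lines and Tap1, a peptide transporter for antigen presentation that is also a p53 target, was higher (1.12 and 2.69).

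The BCL-2 family, which holds the proteins that act upstream of BAX and BAK, had medians of 0.05 and 0.11 over 15 members, at percentile 66.5. Its pair median was 0.05, and 0.49 among the brighter members left by the stricter filter. Within the family Pmaip1 was higher in both lines and Bnip3, a mitochondrial BH3-only gene, was lower (-1.19 and -1.72). Another probe set of Bnip3 gave -0.60 and -1.35. Further lists had medians that differed in sign between the lines. So did the median of all genes kept, at -0.08 in GFP cells and 0.10 in p63 cells. The change of sign is thus not particular to these lists. DNA repair genes stood at -0.14 in GFP cells and 0.21 in p63 cells over 39 members, with a pair median of 0.06 (percentile 81.6), and held Top2a, a target of etoposide, lower (-1.02 and -1.21) and the mismatch repair gene Msh6 higher (1.28 and 1.14). Redox genes, among which Gss, glutathione synthetase, was higher (1.25 and 1.55), stood at -0.01 and 0.29, with a pair median of 0.16 (percentile 97.1). The unfolded protein and ATF4 response stood at -0.02 and 0.12, with a pair median of 0.08 (percentile 88.7) and Atf3, Sesn2 and Ddit4 called higher. Autophagy genes, with Ulk1 (1.47 and 1.76) and Dram1 (1.26 and 1.92) called higher, stood at -0.05 and 0.20, with a pair median of 0.10 (percentile 91.8). Heat shock genes, with Cryab higher (1.32 and 1.59), stood at -0.18 and 0.03, with a pair median of -0.05 (percentile 27.7). Without the array of mock-treated p63 cells the values in GFP cells are what remains of these medians. Some lists share members, so their calls are not separate results. Fas, Btg2, Pmaip1, Sesn2 and Dram1 are on the p53 target list as well. Atf3 is also on the immediate early list and Top2a on the G2/M list. Cathepsins and lysosomal genes, of which 0 of 19 were called in both lines, stood at 0.06 and 0.28 (percentile 86.4), cholesterol synthesis genes at -0.20 and -0.14 (percentile 5.58) and fibroblast matrix genes at -0.20 and -0.01 (percentile 17.1). The Notch list had medians of 0.08 in GFP cells and 0.06 in p63 cells but a pair median of -0.07 (percentile 20.8), with a mean of 0.23, and held 3 genes that were higher in both lines: the receptors Notch1 (1.65 and 1.24) and Notch3 (2.13 and 1.62) and the feedback regulator Nrarp (1.30 and 1.22, or 0.75 and 1.22 with its dim reading raised to the filter). Epithelial genes bound or regulated by p63 had medians of 0.51 in GFP cells and 0.20 in p63 cells and a pair median of 0.36 (percentile 99.97), with Grhl3 higher in both lines, a direction that reversed to -0.01 among the brighter genes left by the stricter filter. With readings below the filter raised to it, this median was 0.16.

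The array of mock-treated p63 cells stood apart from the rest, with 78 genes at least 1 from each of the other arrays while those lay within 0.5 of one another, against 22, 1 and 2 for the others. The split of calls within each line depended on scaling. In p63 cells the share higher was 82.6% as deposited and 60.7% (406 higher and 263 lower) with arrays centred on their medians. In GFP cells it went from 62.4% to 74.0% (469 and 165). Among genes called in both lines the share higher was 80.9% as deposited, 78.6% with arrays centred and 82.7% after cyclic loess.

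**Figure D2:**
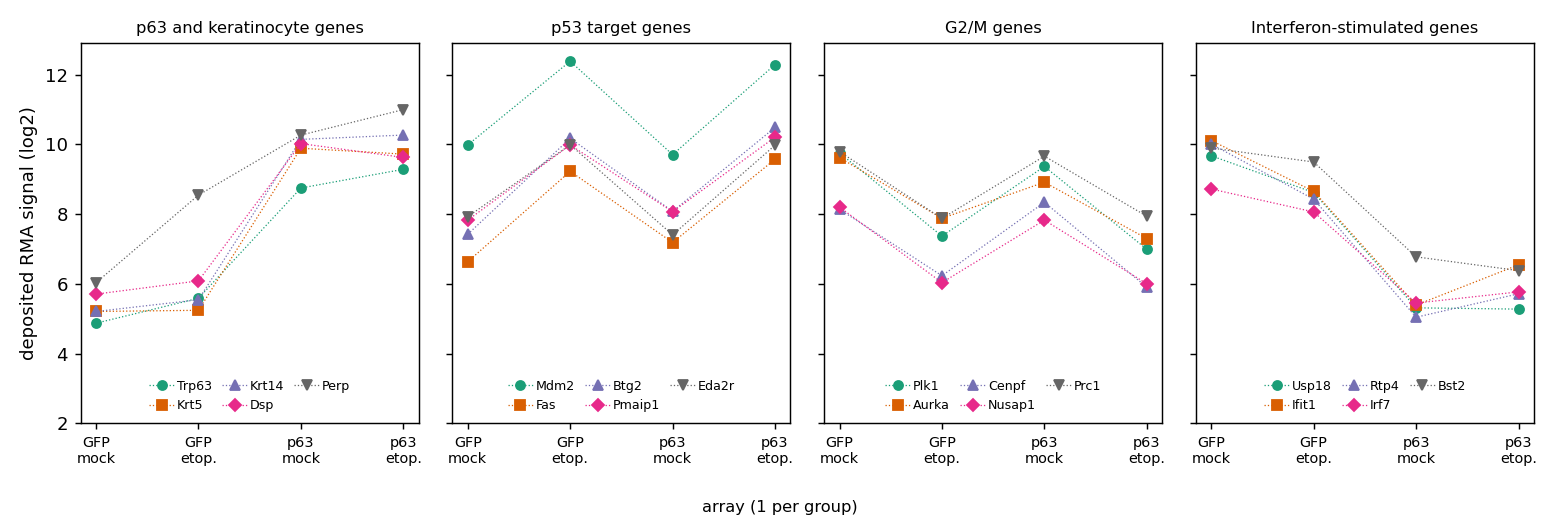
Deposited RMA signal (log2, y axis) of 5 genes from each of 4 groups on the 4 arrays (x axis, 1 array per condition), with dotted lines joining the values of a gene. Mdm2 reads 9.99, 12.39, 9.71 and 12.29, and Krt14 5.21, 5.55, 10.15 and 10.27, from left to right.

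The comparison of p63 with GFP asks what p63 alters in these fibroblasts, at baseline and after etoposide. Of the epithelial genes bound or regulated by p63, 11 of 25 were higher in p63 cells under both treatments, and of the interferon-stimulated genes 19 of 36 were lower. Krt14 and Krt5, the keratin pair of basal epidermis, were higher by 4.94 and 4.68 in mock-treated cells and by 4.72 and 4.48 in etoposide-treated cells, and both read below the filter in GFP cells. Raised to the filter, these readings gave at least 19.4-fold and 16.2-fold in mock-treated and at least 21.1-fold and 14.4-fold in etoposide-treated cells. Igfbp2, an insulin-like growth factor binding protein gene, differed by 5.48 and 5.27, or by 5.22 and 5.27 with its reading in mock-treated GFP cells raised to the filter, the highest difference under that setting. Usp18, an interferon-induced protease that removes ISG15, had log2 differences of -4.36 and -3.34, or of -3.80 and -2.75 with its readings in p63 cells, which were below the filter, raised to it. In etoposide-treated cells that is at least 6.73-fold lower.

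In mock-treated cells 661 genes differed between p63 and GFP by at least 1, 259 higher and 402 lower with p63. In etoposide-treated cells 203 did so, 148 higher and 55 lower. The lists shared 99 higher and 52 lower genes, against 3.58 and 2.07 for independent lists, and 0 genes were called in opposite directions. With readings below the filter raised to it, 101 genes were shared, 70 higher and 31 lower. The Pearson and Spearman correlations across genes were 0.588 and 0.390. Epithelial genes among the highest shared differences also included Serpinb5, the serpin maspin (5.37 and 4.60), Dsp, desmoplakin (4.32 and 3.54), Perp, a desmosomal protein and p53-family target (4.23 and 2.45), Krt16 (3.58 and 3.06) and Krt19 (3.49 and 3.05). Anxa8 (3.90 and 2.46), Ly6d (2.93 and 3.39) and the amino acid transporter gene Slc7a8 (2.49 and 3.27) followed. Serpinb5, Krt16 and Slc7a8 read below the filter in GFP cells, and with those readings raised to it differed by 2.82 and 3.39, 1.75 and 2.46, and 0.82 and 1.91.

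**Figure D3:**
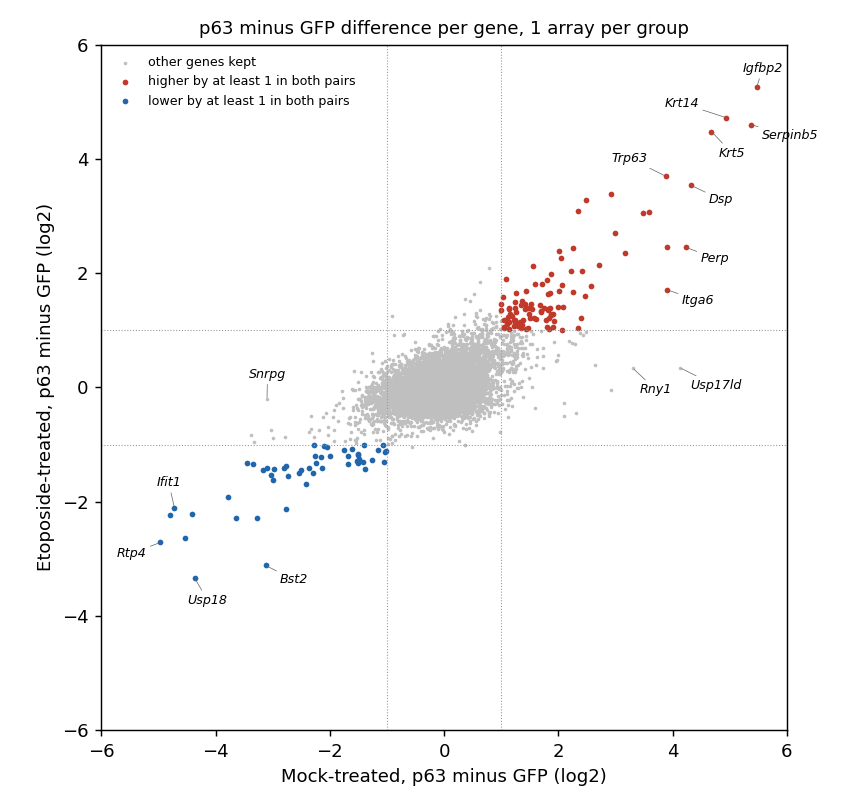
Each point is 1 of the 10698 genes kept, with its p63 minus GFP difference (log2) in mock-treated cells on the x axis and in etoposide-treated cells on the y axis. The 99 genes higher and the 52 genes lower by at least 1 under both treatments are coloured, and Rny1, Usp17ld and Snrpg lie far from 0 in mock-treated cells only.

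Of the 25 epithelial genes bound or regulated by p63, 11 were higher under both treatments and 0 were lower under either, with medians of 1.35 and 0.95 (percentile 100). They included the hemidesmosome integrins Itga6 (3.90 and 1.71) and Itgb4 (1.29 and 1.07), the laminin-332 chains Lamb3 (1.60 and 1.81) and Lama3 (1.35 and 1.13), the growth factor receptor Fgfr2 (2.47 and 1.60), Krt17 (2.05 and 2.27) and the plakophilin Pkp1 (1.35 and 1.04). A gene passed the filter by its highest array, so members could be kept for their signal in p63 cells alone. Without a filter, which takes all 36 members measured, the pair median was 0.71, against 1.18 with it. On this list 17 members read below the filter on at least 1 array. With such readings raised to it, 8 were higher under both treatments, the medians were 0.64 and 0.71, and Krt17 (0.53 and 1.499), Lama3 (0.16 and 0.60) and Itgb4 (0.95 and 1.07) were no longer called under both. Notch pathway genes had medians of 0.58 and 0.18 (percentile 100), and the ligands Jag1 (2.02 and 1.69) and Dll1 (1.53 and 1.45) were the 2 of 19 called under both treatments, and Jag1 the 1 so called with dim readings raised to the filter, where Dll1 stood at 0.66 and 0.72. Cholesterol synthesis genes had medians of 0.29 and 0.50 (percentile 100), with 0 of 20 called under both treatments. The highest were Hmgcs1 (0.85 and 1.13), Sqle (0.73 and 1.09) and Hsd17b7 (0.35 and 1.29). Fibroblast and matrix genes, 30 in number, had medians of 0.07 in mock-treated (percentile 99.8) and 0.10 in etoposide-treated cells (percentile 93.9). Their pair median was 0.22 (percentile 100), against 0.10 without the array of mock-treated p63 cells, and Myl9, a myosin light chain gene, was called (1.72 and 1.81). Of the 7 simple epithelial markers kept, Krt19 was called under both treatments, and the list's pair median was 0.36 (percentile 99.4), against 0.21 with dim readings raised to the filter, 0.09 without a filter and 0.19 (percentile 92.4) without the array of mock-treated p63 cells.

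Interferon-stimulated genes had medians of -2.31 in mock-treated and -1.05 in etoposide-treated cells (percentile 0.00). Of 36 members, 19 were lower under both treatments, 0 were higher under either, and 35 had a negative difference under both. Rtp4 stood at -4.97 and -2.71, Ifit1, which binds viral RNA, at -4.72 and -2.11, Oasl2 at -4.40 and -2.22, Irf7, a transcription factor that drives interferon genes, at -3.27 and -2.29, and Bst2, the restriction factor tetherin, at -3.12 and -3.12. Gbp3 (-4.53 and -2.63), Mx2 (-3.65 and -2.28), Xaf1 (-3.78 and -1.91) and Ifit3 (-3.44 and -1.33) were further members. Trim30a (-4.79 and -2.23) and the chemokine gene Ccl5 (-2.77 and -2.13), the latter from the NF-kB list, completed the 12 lowest. Usp18, Rtp4 and Ifit1 read 9.68, 10.01 and 10.11 in mock-treated GFP cells, against 5.31, 5.04 and 5.39 in mock-treated p63 cells, below the filter. Ifit3 and Mx2 were dimmer, at 7.55 and 7.13 in mock-treated and 4.64 and 6.58 in etoposide-treated GFP cells. On the interferon list 22 members read below the filter on at least 1 array, and with such readings raised to it the medians were -1.39 and -0.64 and 11 members were lower under both treatments. Ifit3 (-1.67 and 0.00), Mx2 (-1.26 and -0.71), Xaf1 (-2.58 and -0.95) and, outside the list, Trim30a (-2.59 and -0.92) were then no longer so called. Of 17 haematopoietic markers, which would accompany blood cells, 14 read below the filter on every array. The 3 others, Cd14, Cd68 and Itgb2, had medians of -0.79 in mock-treated and 0.10 in etoposide-treated cells and a pair median of -0.38 (percentile 2.32), where that of all 17 was 0.01.

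G2/M genes had medians of -0.39 and -0.24 with p63 (percentile 0.01), although 0 of 37 reached 1, and Aurkb (-0.81 and -0.71) and Ube2c (-0.82 and -0.56) were the lowest. NF-kB and inflammatory genes stood at -0.51 and -0.07 (percentile 0.88), S phase genes at -0.36 and -0.02 (percentile 1.41), with Cdt1 at -1.44 and -0.29, and the unfolded protein list at -0.21 and -0.06 (percentile 1.00), with Shmt2 at -1.30 and -0.56. Without the array of mock-treated p63 cells, the values after etoposide are what remains of every pair median with p63. The p53 targets stood at -0.23 and 0.07, with a pair median of -0.08 (percentile 45.9) and a mean of 0.07, and Perp was the 1 of 37 called under both treatments. The BCL-2 family had a pair median of 0.01 (percentile 81.5), a median of 0.02 after etoposide and a pair mean of -0.02, with Bid at -1.09 and 0.14. Death receptor and caspase genes, with the receptor gene Tnfrsf1b at -1.53 and -0.89, had a pair median of -0.11 (percentile 25.3) and a median of -0.03 after etoposide, and histones had -0.16 (percentile 8.48) and -0.14. Other lists had medians that differed in sign between the treatments. The median of all genes kept did so too, at -0.14 in mock-treated and 0.02 in etoposide-treated cells. A change of sign alone is thus not particular to these lists. DNA repair genes, with Fancd2 at -0.96 and -0.29, stood at -0.34 in mock-treated and 0.02 in etoposide-treated cells (pair median -0.15, percentile 9.28), and redox genes, with Slc7a11 at -0.91 and -0.85, at -0.38 and 0.02 (pair median -0.19, percentile 3.86). Immediate early genes, with Fosl1 at -1.67 and -0.54, stood at -0.38 (percentile 0.32) and 0.22 (percentile 99.97), with a pair median of -0.08 (percentile 37.5). Cathepsins and lysosomal genes, with Ctsl at 0.88 and 0.46, stood at -0.02 and 0.09 (pair median 0.05, percentile 95.1) and autophagy genes at -0.07 and 0.17 (pair median 0.05, percentile 98.3). Heat shock genes, with Hspa4l higher (1.25 and 1.40), stood at -0.12 and 0.10 (pair median -0.03, percentile 78.9, mean 0.06).

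In mock-treated cells the direction of the p63 calls depended on scaling. Their share higher was 39.2% as deposited, 66.9% with arrays centred (408 higher and 202 lower) and 58.7% after cyclic loess (333 and 234), and the median of all genes in this comparison moved from -0.14 to 0.07 on centring and 0.01 on loess.

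The design also asks whether p63 alters the response to etoposide. The differences of interest are the etoposide difference in p63 cells minus that in GFP cells, called the interaction. Interferon-stimulated genes had high values: their median etoposide difference was -0.99 in GFP cells and 0.04 in p63 cells. Perp and Itga6, which were higher after etoposide in GFP cells, had low values. Ifit1 stood at -1.46 after etoposide in GFP cells and 1.15 in p63 cells, an interaction of 2.61. With its dim reading raised to the filter the difference in p63 cells was 0.68 and the interaction 2.14. Cxcl10, a chemokine gene induced by interferon and NF-kB, was higher by 0.55 in GFP cells and by 3.10 in p63 cells, an interaction of 2.55.

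The interaction reached 1 for 421 genes, 304 with a higher and 117 with a lower value in p63 cells. With readings below the filter raised to it, 324 genes reached 1, 262 higher and 62 lower. Of 36 interferon-stimulated genes, 21 had a value of at least 1 and 0 of -1 or less, with a median of 1.11 (percentile 100), or 0.82 with readings below the filter raised to it. Besides Ifit1 they included Rtp4 (2.25), Oasl2 (2.18) and Ifi203 (2.29), the last at 0.14 with its readings below the filter raised to it, and outside the list Trim30a (2.56, or 1.67 with dim readings raised) and Parp14 (2.38) had similar values. Parp14 stood at -2.37 after etoposide in GFP cells and 0.01 in p63 cells, where its signal was below the filter on both arrays (5.57 and 5.58). Immediate early genes had a median of 0.58 (percentile 100) with 9 of 36 at 1 or more, among them Myc (1.73), Dusp6 (1.49) and Fosl1 (1.13), and NF-kB genes a median of 0.47 (percentile 99.8) with 7 of 25, among them Nfkbia (1.31) and Ccl2 (1.07). Epithelial genes had a median of -0.31 (percentile 0.01), which was -0.05 with readings below the filter raised to it. Perp was higher by 2.51 after etoposide in GFP cells and by 0.73 in p63 cells, where it already read 10.27 before the drug. Itga6, the integrin subunit, was higher by 1.83 in GFP cells and stood at -0.36 in p63 cells. The BCL-2 family had a median of -0.13 (percentile 0.52) and a mean of 0.08, with 1 member at 1 or more and 0 at -1 or less, and a bootstrap interval of the median, -0.29 to 0.22, that held the 0.20 of all genes. Notch genes had a median of -0.19 (percentile 0.12), while p53 targets were at 0.25 (percentile 63.1) and G2/M genes at 0.26 (percentile 64.6).

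Further extreme values came from the array of mock-treated p63 cells. Snrpg, a spliceosomal protein gene (2.89), and Usp17ld (-3.78), the Ro-associated Y RNAs Rny1 (-2.97) and Rny3 (-2.61), Tns1 (-2.77), Myo18b (-1.95) and Rprl1 (-1.55) differed between p63 and GFP cells by 1.38 or more in size when mock-treated and by 0.51 or less when etoposide-treated. Another probe set of Snrpg gave 0.34, the others of Tns1 ran from -0.60 to 0.46, and the others of Myo18b from -1.67 to 0.26. Myc met the same bounds, with p63 minus GFP differences of -1.79 when mock-treated and -0.06 when etoposide-treated. For Dusp6 these were -1.03 and 0.46, for Nfkbia -0.91 and 0.40, and for Ccl2 -1.68 and -0.615. The list medians were -0.38 and 0.22 for immediate early and -0.51 and -0.07 for NF-kB genes. These interactions thus also lie mainly in the mock-treated pair, which holds the array of mock-treated p63 cells. The split of interaction calls depended on scaling, at 72.2% higher as deposited, 19.8% with arrays centred (84 higher and 341 lower) and 55.8% after cyclic loess (164 and 130), and the median of all genes moved from 0.20 to -0.10 and 0.00. The medians of the interferon, immediate early and NF-kB lists stayed above 0 under both scalings, at 0.81, 0.29 and 0.18 with arrays centred and 0.98, 0.45 and 0.42 after loess.

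**Figure D4:**
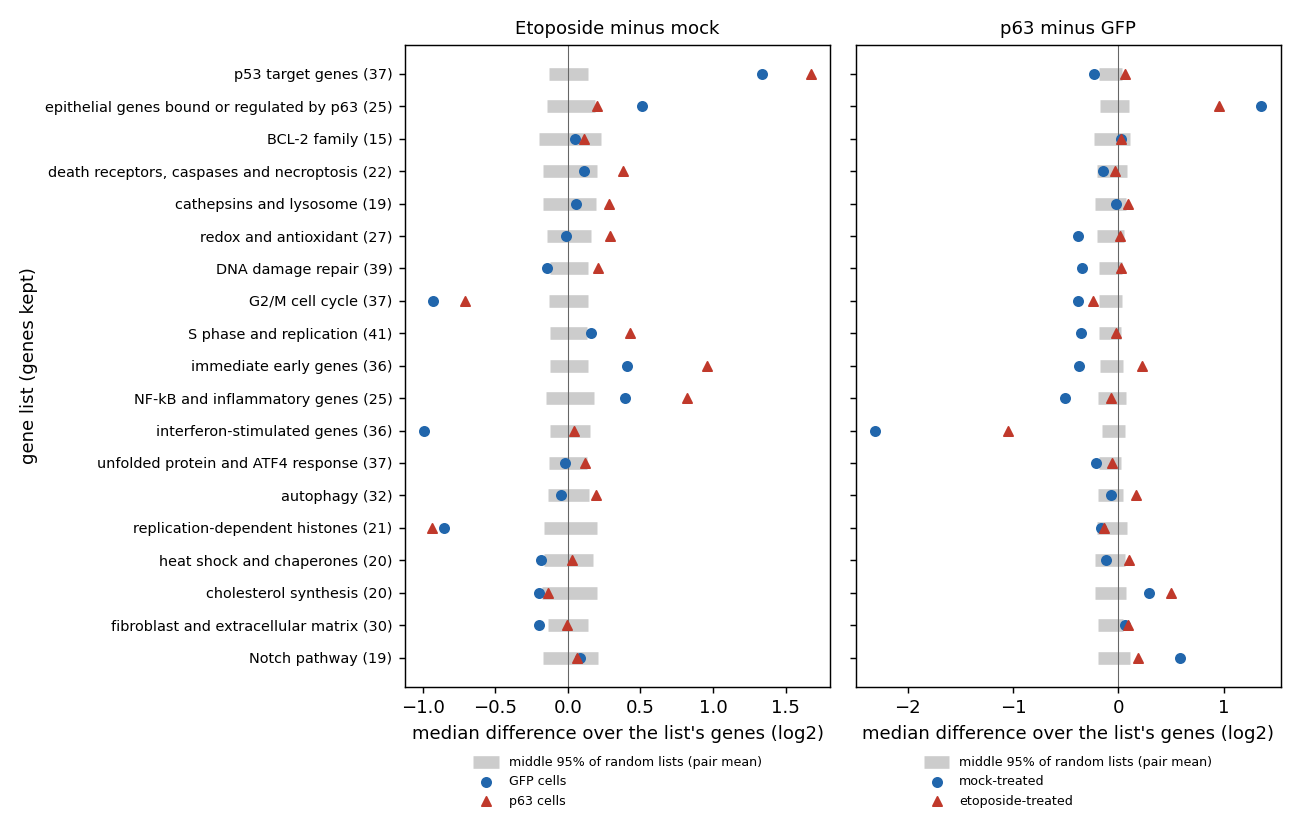
Median difference (log2, x axis) over the genes kept of each list (y axis, number of genes in brackets), for etoposide minus mock on the left (circles GFP cells, triangles p63 cells) and p63 minus GFP on the right (circles mock-treated, triangles etoposide-treated). Grey bars span the middle 95% of random lists matched on expression, for the mean of the pair, and the interferon list reads -0.99 and 0.04 on the left and -2.31 and -1.05 on the right.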

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

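All tests in this part were chosen after the results were seen. Genes whose etoposide difference went in opposite directions in GFP and p63 cells, by at least 1.5-fold in each, drew attention as a difference between the lines, and with 1 array per condition these differences were not tested. Ifit1 stood at -1.46 in GFP cells and 1.15 in p63 cells, a gap of 2.61, and Trim30a at -1.67 and 0.89, a gap of 2.56. Rtp4, at -1.58 and 0.67, had a gap of 2.25, and Irgm1, a GTPase gene induced by interferon, at -1.14 and 0.86, a gap of 1.996. Myc, the growth regulator, stood at -0.73 and 1.00, a gap of 1.73. Its p63 minus GFP difference was -1.79 when mock-treated and -0.06 when etoposide-treated. The gap thus lies in the mock-treated pair, which holds the array of mock-treated p63 cells.

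Ifit1, Rtp4 and Irgm1, and Trim30a from outside the list, go with a wider pattern, a less negative etoposide difference of interferon-stimulated genes in p63 cells, where 19 of the 36 members on the list had a mean below the filter and a further drop would be hard to see. The 17 members whose mean over the p63 arrays reached the filter had a median interaction of 0.92, with a bootstrap interval of 0.19 to 1.58 that held the 0.20 of all genes. Over the list the median etoposide difference in p63 cells was 0.04 against 0.10 for all genes, and Rtp4 and Trim30a read below the filter on both p63 arrays. A signal near background and a different response in p63 cells therefore both stay open. The array of mock-treated p63 cells enters every interaction.

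That array, the pattern to check before others, lay at least 1 from all other arrays for 20 genes in the higher and 58 in the lower direction. Cyclic loess removes a trend with brightness. With the arrays' medians put back as deposited, which keeps each array's level, it left 17 of those 20 and 57 of those 58 genes. Cyclic loess without that step left 19 of the 20 and 25 of the 58. Few of the 20 higher genes were lost either way, which argues against a compressed signal for them. For the 58 lower genes the test cannot decide, because compression can itself lower the array's median among the genes kept, which was put back. Centring, which moves the level alone, left 18 of the 20 and 16 of the 58, so the number of lower genes depended on the level of this array. With arrays centred this array stood apart for 37 higher and 16 lower genes in all, and after cyclic loess for 25 and 25. Which direction held more genes thus depended on scaling. Of the 20 higher genes 8 were small non-coding RNA genes, a class that made up 1.32% of genes, and 0 of the 58 lower genes were. The 141 such genes had a median deviation of 0.29 on this array (bootstrap interval 0.17 to 0.39), in the direction of more small RNA in its labelled material. They include those 8, and some passed the filter on this array alone, which favours a higher median. Among bright members Rmrp and Rn7sk went the other way, at -0.31 and -0.13, while Rpph1 and Rny3 stood at 0.65 and 2.22. The median therefore does not decide for this explanation, and a response of unstressed p63 cells stays open as an untested biological one.

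The lower interferon-stimulated genes in p63 cells are a separate pattern. In the etoposide-treated pair, which does not hold the array above, the list's median was -1.05, below the middle 95% of random lists, so that array alone does not account for it. Blood cells in the GFP cultures would bring their abundant transcripts, yet Lyz2 (3.43), Ptprc (3.95) and Tyrobp (4.65), named after their values were seen, lay below the filter in mock-treated GFP cells, where the 17 haematopoietic markers had a median signal of 4.17 and the interferon list one of 8.17. The median p63 difference of these markers was 0.01 (bootstrap interval -0.22 to 0.21) against -1.69 for the interferon list. As 14 of the 17 read below the filter on every array, that difference could hardly depart from 0 and decides nothing. The low signal of the markers in GFP cells argues against blood cells as the source. Against this, the 3 markers above the filter on any array had a pair median of -0.38. Among them Cd68 read 6.05 in mock-treated GFP cells, with a p63 difference of -0.86 there. An effect of p63 and a difference between the GFP and p63 cultures in their response to retroviral transduction stay open, as 1 culture of each was used and cells without virus were not analysed here.

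Probe sets without a single gene symbol lie outside the comparisons and also carried signal. Of 5911 that passed the filter, 127 differed by at least 1 after etoposide in both lines, 28 higher and 99 lower, a split opposite to that of named genes (275 and 65). With p63, 70 differed under both treatments, 46 higher and 24 lower. Among the 5088 that the annotation did not list, 24 were higher and 93 lower after etoposide and 44 higher and 12 lower with p63. Among the 823 with several symbols these numbers were 4, 6, 2 and 12.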

How the results depend on the processing

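The results without the array of mock-treated p63 cells, the list medians with dim readings raised to the filter, and the numbers of genes apart with arrays centred or with cyclic loess at the deposited medians were added after the data were seen. Of 77 recomputed counts and correlations, 51 stayed within 1.5 times the value in the report or, for correlations, within its bootstrap interval, and 26 moved. At the 75th percentile filter, which leaves fewer genes, 364 genes differed after etoposide in GFP cells (604 in the report), 535 in p63 cells (814), 407 with p63 in mock-treated cells (661), 120 in etoposide-treated cells (203), 95 with p63 under both treatments (151), and 211 by the interaction (421). At 1.5-fold these were 2007, 2354, 2441, 725, 428 and 2312, and 987 genes differed after etoposide in both lines (340). Without a filter the interaction reached 784 genes, 336 higher and 448 lower. With readings below the filter raised to it, 475 genes differed after etoposide in GFP cells and 701 in p63 cells. With p63, 526 then differed in mock-treated and 152 in etoposide-treated cells. Without the array of mock-treated p63 cells, etoposide rests on GFP cells alone (604 genes) and p63 on etoposide-treated cells alone (203). The correlation of etoposide differences (0.629) was 0.424 without a filter, 0.729 at the stricter filter and 0.655 after loess, and that of p63 differences (0.588) was 0.344 and 0.726 at those filters. After loess the arrays of p63 cells stood apart for 50 (mock) and 4 (etoposide) genes, against 78 and 2. With arrays centred those of etoposide-treated GFP and p63 cells stood apart for 0 genes each, and with loess at the deposited medians for 4 and 8, against 1 and 2. The shares higher that scaling moved by over 10 points stand in the report. Of 479 list medians 415 stayed within their interval, 59 moved and 5 reversed: epithelial genes after etoposide at the stricter filter (-0.008), the unfolded protein list's interaction with arrays centred (-0.25) and after loess (-0.11, from 0.04), and haematopoietic markers with p63 without a filter (0.01) and without the array of mock-treated p63 cells (0.10, from -0.38). Of 1523 values of named genes, 96 moved and 0 reversed, 65 of the 96 with dim readings raised to the filter. Where no cause is evident from the setting, the cause was not tested. Signal over background limits genes near 5.87. No paired analysis was possible because the groups share 1 replicate number, if pairs are taken by that number. Pairing by cell line or treatment is the additive model of treatment and virus, which could be fitted with 1 residual degree of freedom and was left out by choice.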

Other observations

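The test of gene length was planned before its result was seen, and the overlap of the effects was examined after the counts. The mean etoposide difference and the mean p63 difference were close to uncorrelated across genes, with a Pearson correlation of 0.01 and a Spearman correlation of -0.08. Of the genes called in both pairs of each effect, 11 were higher by both, against 2.55 for independent lists. With readings below the filter raised to it, a setting added after the data were seen, 3 of the 11 remained, Ces2e, Rflnb and Rgs12, against 1.45 for independent lists. Both effects were taken from the same 4 arrays. Unchanged groups simulated 100 times on such arrays had a mean Pearson correlation of 0.0002 and a mean covariance of 0.0000. The observed covariance was 0.0011. Every simulated array had the same noise, and in this balanced design equal noise leaves the mean differences uncorrelated by construction. The simulation therefore cannot say what arrays with unequal noise add here. The simulated groups gave 0 genes called by both effects, which says nothing of the overlap. At this noise 0 of 10152 simulated unchanged genes were called in both pairs of either effect. The 11 were the neighbouring carboxylesterase genes Ces2e, Ces2f and Ces2g, the G protein subunit gene Gna15, Gpx6, Lhfpl1, Ly6d, Rflnb, Rgs12, a regulator of G protein signalling, Stox2 and Vnn1, the pantetheinase vanin, which were chosen after their values were seen, apart from Ces2g and Ly6d. The mean p63 difference was 3.16 for Ly6d, 1.84 for Stox2, 1.49 for Ces2f, 1.40 for Ces2g and 1.25 for Ces2e. Atxn1, Lgr4, Mecom and Npy1r, 4 genes against 0.60 for independent lists, were lower after etoposide and higher with p63, and with dim readings raised Npy1r was no longer so called and the other 3 remained, against 0.347. Ptx3 was lower by both and an olfactory receptor gene, Olfr767, higher and lower. These too, except Npy1r, were named after their values were seen.

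Markers of other cell types were mostly dim. Simple epithelial markers had a pair median of 0.49 after etoposide (percentile 98.4, 7 genes), with St14, the protease matriptase, higher in both lines (1.13 and 1.41). With readings below the filter raised to it the median was 0.14 and St14 stood at 0.47 and 0.88, with 0 members higher in both lines, and without a filter the median was 0.18. The 3 haematopoietic markers kept, Cd14, Cd68 and Itgb2, had a pair median of 1.20 after etoposide (percentile 99.8), and Cd14, a receptor for lipopolysaccharide, was higher by 1.70 and 2.03, or by 1.41 and 0.95 with its dim readings raised to the filter. Without a filter the median etoposide difference of all 17 markers was 0.21. The pair median of the 3 with p63 was -0.38 (percentile 2.32). Without the array of mock-treated p63 cells these medians were 0.75 and 0.10. Endothelial markers (3 genes) had pair medians of -0.05 with etoposide and 0.22 with p63 (0.15 and -0.10 without that array), skeletal muscle markers (7 genes) 0.10 and 0.11 (0.32 and 0.02), adipocyte markers (3 genes) -0.13 and 0.09 (0.27 and 0.13), and neural markers (3 genes) 0.17 and 0.17 (0.42 and 0.34). Both endothelial medians and the adipocyte median with etoposide thus took the opposite sign without that array. The percentiles with all arrays lay between 23.4 and 88.8.

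Topoisomerase II poisons could lower transcripts of long genes in particular, and this was tested as a hypothesis for the genes lower after etoposide. It required a Spearman correlation of the etoposide difference with gene length below -0.1 in both lines. The correlation over 10693 genes was -0.13 in GFP cells and -0.013 in p63 cells, so the hypothesis failed in p63 cells. The difference in p63 cells holds the array of mock-treated p63 cells, which stood apart, and how far that array set this result was not tested. Length correlated with the p63 minus GFP difference at 0.016 in mock-treated and 0.198 in etoposide-treated cells. The median length was 24.2 kb for the genes lower in both lines and 22.7 kb for all genes kept. The longest of 10 groups of genes by length went toward the hypothesis, with 13 of the genes lower in both lines against 4 to 9 in the other groups, and with median etoposide differences of -0.20 in GFP cells and -0.01 in p63 cells, where the medians over all genes kept were -0.08 and 0.10.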
